A study of Homo sapiens with 8 samples.

How the data were processed

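RNA was measured in KPL-1, a human breast cancer cell line that carried a doxycycline-inducible Cas9 (iCas9). There were 6 libraries, 3 from cells with an empty guide vector (sgEmpty) and 3 from cells with a guide against SETD1A (sgSETD1A), all from day 7 of doxycycline. The labels describe culture in DMEM with serum, column extraction with DNase and a stranded mRNA library kit. In the same line, a pool of guides (sgKMT2pool) was counted in 1 library at day 0 and 1 library at day 14. The labels repeat the RNA protocol for both pool libraries, and how guides were amplified for counting is not given in the sources used here. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

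The expression table held TPM values (transcript abundance scaled to a common total) deposited by the authors for 19035 gene symbols. The submitters' processing notes name bcl2fastq 2.20.0, STAR 2.6.0c and RSEM 1.3.1 and the hg19 build, without saying which step used which. A last row with no gene name held 1000000 in each library, the column total, and was left out of every step. TPM keeps no sequencing depth, so the depth of the RNA libraries is unknown here and no count test was run. Of the symbols, 17039 were current in the gene name tables given for this work, which use the GRCh38.p14 assembly, 1788 older ones matched a single current symbol as synonyms, and 208 did not match. No coordinates are printed, because the builds differ.

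The guide table held raw read counts per guide as deposited by the authors, for 5995 guides. The row with the column totals named no guide and was left out; it equalled the sum of the others, so its share was the whole of the reads. Totals were 10145466 reads at day 0 and 10255022 at day 14, with medians of 1531 and 1289 reads per guide. These reads carry no molecular identifiers, so intervals of single guides cover counting error only; the median counting error of a log2 ratio was 0.056.

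Expression was compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(TPM + 1) of genes with a mean TPM of at least 1 over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. On simulated data with 11885 genes, 200 of them changed, this fit called 44% of genes changed by 0.3 log2, 76% at 0.5, 94% at 1 and 100% at 2, and 3.68% of its calls were false. The simulation drew genes independently of one another, and 41.5% of tested genes were called in the data, so its rates need not hold there. The 23 gene lists were fixed before the data were examined. The 21 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with fry and on ranks. Each list's median was also placed among 10000 random lists matched on mean expression.

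In the guide table, the change of a guide was the log2 ratio of CPM (reads scaled to a common total) plus 1, day 14 over day 0, for guides with at least 30 reads at day 0, which left 5991. The median of 200 guides whose names begin with HGLibA was subtracted. That prefix is the naming of a genome-wide human guide library, and the reading of these guides as non-targeting controls rests on background knowledge, since the table does not say it. Names KMT2F and KMT2G are synonyms of SETD1A and SETD1B in the RefSeq table. The number in each guide name was read as a nucleotide position in the coding sequence, from the range of the numbers; the table does not define it, so every residue given here depends on that reading. Windows of 100 residues with at least 3 guides were summarised by their median. With 1 library per day there is no replicate check, and no p-value is given. The median of a target was placed among 10000 random lists drawn from all 5991 guides, its own included, matched on day 0 reads in 5 bins. That of a window was placed among 10000 random lists of guides of the same gene. Intervals of medians are exact 95% order-statistic intervals over guides, and those of shares of guides, and of the reads of single guides, are exact Clopper-Pearson 95% intervals. Intervals of medians and of shares of guides cover the spread between guides in these libraries, not that between cultures. On 5995 simulated guides the medians of the targets were recovered within 0.042 log2. That simulation gave all guides of a target the same shift and added counting noise only. It leaves out the spread between guides, so real medians are less certain than that. The 3 guides named for 2 positions were kept for their gene and left out of windows, and 376 rows that share a name with another row were kept as separate guides.

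Named transcripts were SETD1A, CCNK, CDK12 and CDK13, and the 12 largest rises and 12 largest falls with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap between groups. Up to 4 called members of each list, by size of change, were added, or 2 with the smallest p where none was called. In the screen the rule named every tiled gene, the control guides as a class, the 3 lowest SETD1A windows, the lowest window of each other tiled gene and the 5 SETD1A guides that fell most. Alternatives covered pseudocounts, filters, scaling, the variance model, a replicate block and leaving out each library, and for the screen the pseudocount, read minimum, centring, averaging and window size. A named transcript and a small set of control guides are not reported here. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the screen and the plots.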

Results

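The study asked what SETD1A, a histone methyltransferase that acts in a chromatin complex, does in breast cancer cells, and its title links this to cyclin K. Transcripts were measured in iCas9 KPL-1 cells at day 7 of doxycycline in 3 sgEmpty and 3 sgSETD1A libraries, and a pool of guides tiled along SETD1A and related genes was counted at day 0 (10145466 reads) and day 14 (10255022 reads), in 1 library each. The depth of the RNA libraries is unknown. Each RNA library listed between 11769 and 11961 genes at 1 TPM or more. Pearson correlations of log2(TPM + 1) were 0.995 to 0.998 between libraries of a group and 0.988 to 0.990 between groups, across genes, which are not independent replicates. Within the sgSETD1A group, replicate 1 stood apart from the others: its correlations with them were 0.9956 and 0.9954, against 0.9977 between them, and on the second principal component (14.3% of the variance) it lay at 12.8, against -5.61 and -6.55.

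The targeted transcript was lower in every sgSETD1A library. SETD1A stood at 17.7 ± 0.31 TPM (SD, n = 3) in sgEmpty and 10.4 ± 0.97 TPM (SD, n = 3) in sgSETD1A, a fall by 0.71 on the log2 scale (SE 0.071; limma adjusted p = 9.13e-05). A Cas9 edit need not lower its transcript, and the share of edited alleles was not analysed here. CCNK, which encodes cyclin K, the partner of the transcription kinases CDK12 and CDK13, went from 85.5 ± 2.58 to 97.8 ± 1.45 TPM (SD, n = 3), a rise of 0.19 log2 (limma adjusted p = 0.00354). This rise stands beside a median change of 0.073 log2 over all tested genes, an offset that median-ratio rescaling removes. CDK12 measured 15.8 ± 0.43 and 16.9 ± 0.71 TPM, and CDK13 17.4 ± 0.58 and 19.1 ± 1.01 TPM (SD, n = 3); neither passed the threshold, with limma adjusted p = 0.211 and 0.107.

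Of 11885 tested genes, 3327 were higher and 1605 lower in sgSETD1A, and 6953 did not pass. Most changes were small: 15 genes rose and 25 fell by at least 1 log2, and without sgSETD1A replicate 1 the first of these counts was 25. These counts depended on the pseudocount, with 82 and 50 genes at a pseudocount of 0.1 and 6 and 6 at 5. The 2 groups did not overlap in 53.7% of tested genes, where chance gives 10% of genes. The balance of rises and falls depended on scaling: 67.5% of calls were higher with TPM as deposited, 43.1% after median-ratio rescaling (1766 higher, 2333 lower) and 51.0% after quantile normalization. The median change of all tested genes was 0.073 log2, and the median of the shifts of single genes under median-ratio rescaling was -0.075. No gene called under both scalings changed direction.

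Genes induced by interferon rose the most. IFIT1 went from 2.91 ± 0.69 to 17.1 ± 0.53 TPM (SD, n = 3), a rise of 2.23 log2 (SE 0.11; limma adjusted p = 3.42e-06). IFI6 went from 69.6 ± 5.49 to 252.9 ± 8.5 TPM (SD, n = 3), or 1.85 log2, IFI27 rose by 1.90, OAS1 by 1.84 and OAS3 by 1.18 log2. The other largest rises were those of the chemokine receptor gene CXCR4, from 32.5 ± 4.26 to 93.8 ± 5.21 TPM (SD, n = 3), the secreted proteins PIP (1.24 log2), IGFBP3 (1.21) and CRISP3 (1.07), the interleukin receptor IL1R1 (1.07), C2orf54, now MAB21L4 (1.05), and UGT1A6 (1.25). UGT1A6 shares exons with other genes of its locus, so its value is uncertain. 

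The largest falls were in genes of varied function. GSTZ1, an enzyme of tyrosine breakdown, went from 135.7 ± 2.49 to 50.1 ± 0.83 TPM (SD, n = 3), a change of -1.42 log2 (SE 0.036; limma adjusted p = 1.00e-07). C11orf1, now CFAP68, changed by -1.51, SPINK4 by -1.45, UNC50 by -1.32 and C6orf52 by -1.27 log2. COQ5, which acts in coenzyme Q synthesis, changed by -1.13, and PET112, now GATB, which acts in mitochondrial translation, by -1.25. CYB5D2 (-1.23), ADPRHL1 (-1.22), C19orf54, now ACTMAP (-1.13), LRRC23 (-1.13) and ZNF572 (-1.12) completed the 12. SPINK4 was the most variable of these, at 8.15 ± 3.76 and 2.24 ± 0.98 TPM (SD, n = 3).

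**Figure D1:**
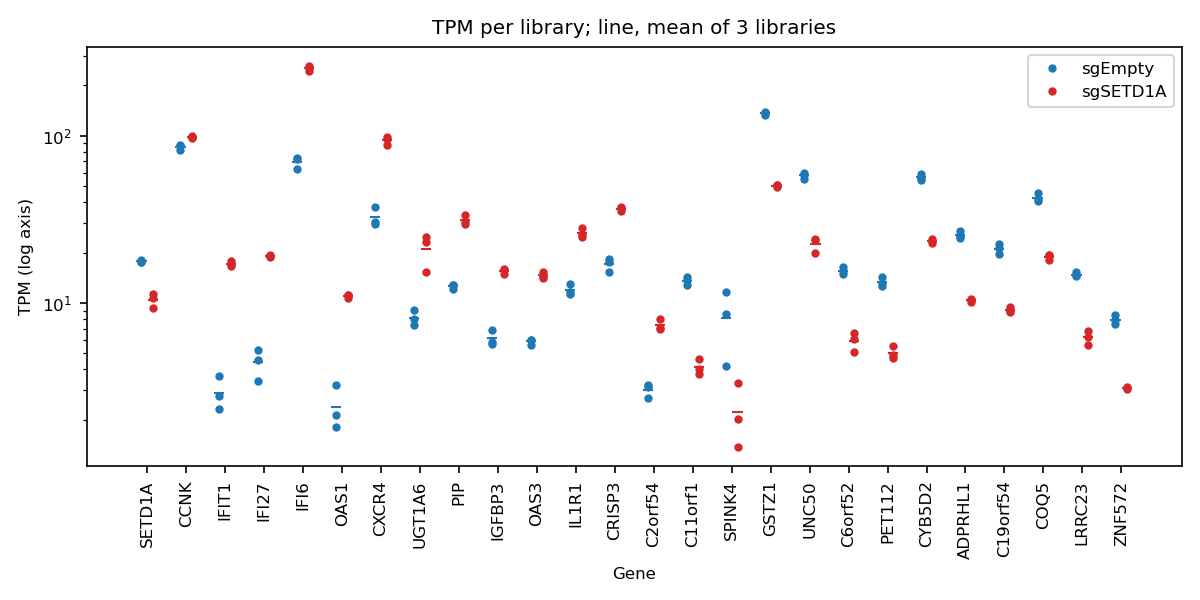
TPM (log axis) of SETD1A, CCNK and the 12 largest rises and 12 largest falls, one point per library and a line at the mean of 3 libraries per group. SETD1A lies near 17.7 TPM in sgEmpty and 10.4 in sgSETD1A, and the groups do not overlap for any gene drawn.

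Among the lists fixed beforehand, that of the interferon response moved most. Of 25 tested interferon response genes, 22 rose, none fell and 3 did not pass; 24 were higher when adjusted over the list alone. The median change was 0.57 log2, above all 10000 random lists matched on expression (camera adjusted p = 1.35e-10; adjusted p = 0.17 with an estimated correlation). IFIT1, IFI27, IFI6 and OAS1 led it, and 21 rose after median-ratio rescaling and 22 after quantile normalization. Of 22 hypoxia and glycolysis genes, 18 rose and 1 fell, with 9 and 2 after median-ratio rescaling and 12 and 1 after quantile normalization; the counts adjusted over the list alone were also 18 and 1. Without sgEmpty replicate 2, 11 rose and 1 fell, and none fell without sgEmpty replicate 1, sgSETD1A replicate 2 or sgSETD1A replicate 3 (16, 14 and 15 rose). Their median was 0.23 log2 (camera adjusted p = 2.50e-04; adjusted p = 0.17 with an estimated correlation). EGLN3, a prolyl hydroxylase induced by low oxygen, rose by 0.80 log2, NDRG1 by 0.62 and BNIP3 by 0.42.

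Ribosomal protein genes and genes of cholesterol synthesis fell. Of 45 ribosomal protein genes, 38 fell and none rose with TPM as deposited (39 fell when adjusted over the list alone). After median-ratio rescaling 42 fell and none rose, and after quantile normalization 26 fell and 3 rose. Their median was -0.15 log2, below all 10000 matched lists (camera adjusted p = 1.08e-19; adjusted p = 0.17 with an estimated correlation). The list took 13.9% to 14.3% of all TPM in sgEmpty libraries and 12.7% to 12.8% in sgSETD1A libraries. RPS2 changed by -0.35, RPL13 by -0.30, RPS3 by -0.30 and RPS6 by -0.26 log2; processed pseudogenes share sequence with such genes, so single values are uncertain. Other genes with a span under 5 kb and a mean of at least 50 TPM had a median of 0.028 log2, against 0.073 for all tested genes. Of 22 cholesterol synthesis genes, 14 fell and none rose, also 14 when adjusted over the list alone and 15 after either rescaling. Without sgEmpty replicate 1, 12 fell and 1 rose. Their median was -0.19 log2 (camera adjusted p = 2.20e-07; adjusted p = 0.18 with an estimated correlation). STARD4, a sterol carrier, changed by -0.67, HSD17B7 by -0.65, SQLE, an early enzyme of sterol formation from squalene, by -0.42 and DHCR7, a late enzyme of the pathway, by -0.40 log2.

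Of the lists of cell cycle genes, that of mitosis was called. Of 40 mitosis genes, 15 rose and 1 fell (16 and 1 when adjusted over the list alone), with a median of 0.12 log2 (camera adjusted p = 0.0368; adjusted p = 0.576 with an estimated correlation). After median-ratio rescaling 8 rose and 1 fell, with a median of 0.040 log2, and after quantile normalization 12 and 1. The call was lost after median-ratio rescaling (camera adjusted p = 0.0949), without sgEmpty replicate 1 (camera adjusted p = 0.0503) and without sgSETD1A replicate 1 (camera adjusted p = 0.160); over 16 alternatives with the preset correlation or ranks the value ran from 0.00561 to 0.160. KIF23 rose by 0.42, UBE2C by 0.41 and NUSAP1 by 0.28 log2, and HMMR changed by -0.35. Of 40 replication genes, 15 rose and 2 fell (15 and 3 when adjusted over the list alone), against 8 and 5 after median-ratio rescaling and 11 and 4 after quantile normalization, and the list was not called (camera adjusted p = 0.234). Its largest changes were falls of RPA3 (-0.83 log2), a subunit of the single-strand binding complex, and PRIM1 (-0.53), a primase subunit, beside rises of RRM2 (0.47) and GINS2 (0.33). Of 20 cyclins and other regulators of the first gap phase, 10 rose and 1 fell (11 and 2 when adjusted over the list alone; camera adjusted p = 0.202), against 6 and 3 after either rescaling and 6 and 1 without sgEmpty replicate 2. CDKN2B, an inhibitor of cyclin-dependent kinases, rose by 0.55 and the transcription factor E2F1 by 0.35 log2, while MYB changed by -0.33.

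DNA repair genes moved both ways: of 38, 9 rose and 6 fell, the same counts when adjusted over the list alone, against 2 and 11 after median-ratio rescaling and 4 and 9 after quantile normalization (camera adjusted p = 0.602). The counts were 6 and 3 without sgEmpty replicate 2, 6 and 2 without sgEmpty replicate 3, 4 and 4 without sgSETD1A replicate 2 and 5 and 4 without sgSETD1A replicate 3. The median was 0.073 log2, while the mean was -0.0021 and the test's direction was down. RAD50, a member of the complex that senses double-strand breaks, changed by -0.90 log2 (SE 0.049; limma adjusted p = 4.25e-06), and the nuclease gene ERCC4 by -0.50 log2. Of 13 genes of cyclin K and other elongation kinases, 4 rose and 1 fell, also when adjusted over the list alone, and 2 rose and 2 fell after median-ratio rescaling (camera adjusted p = 0.591). Without sgEmpty replicate 1 or sgSETD1A replicate 3, as after quantile normalization, 2 rose and 1 fell. LARP7, which binds the small nuclear RNA that restrains transcription elongation, changed by -0.43, HEXIM1, an inhibitor of that step, rose by 0.26 log2. Of 20 genes of SETD1 and KMT2 complexes, 6 rose and 5 fell, also when adjusted over the list alone, and 2 and 5 after either rescaling (camera adjusted p = 0.584). These counts were 3 and 5 without sgEmpty replicate 1, 3 and 3 without sgEmpty replicate 3 or sgSETD1A replicate 2, and 2 and 3 without sgEmpty replicate 2 or sgSETD1A replicate 3. The median was 0.044 log2, while the mean was -0.0065 and the test's direction was down. The list holds SETD1A itself, the target of the guide, which is among the falls (-0.71 log2) and lowers the mean. MEN1 changed by -0.31, NCOA6 by 0.27 and RBBP5 by 0.24 log2.

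**Figure D2:**
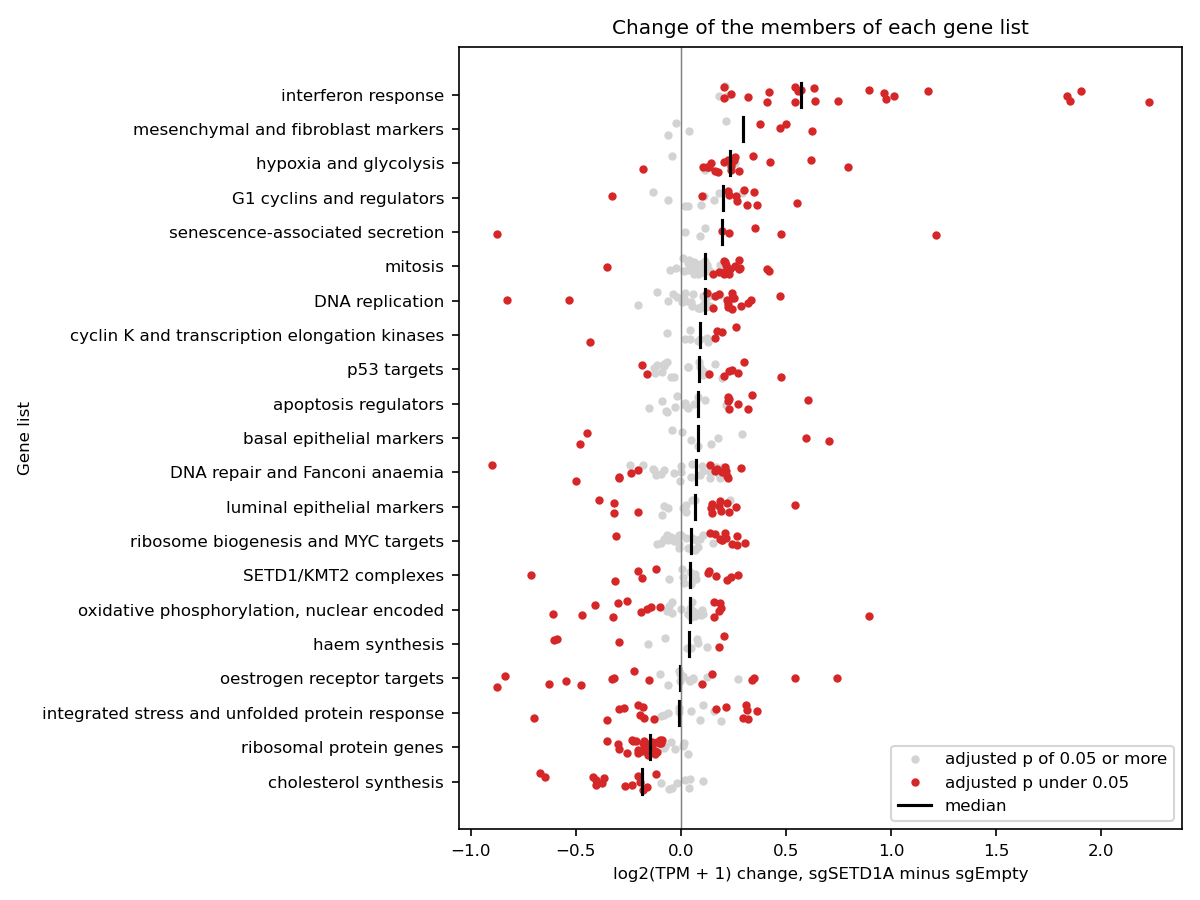
Change in log2(TPM + 1), sgSETD1A minus sgEmpty, of each member of the 21 tested lists, with a black line at the median; red points have an adjusted p under 0.05. The interferon list has the highest median (0.57) and the cholesterol list the lowest (-0.19).

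The oestrogen receptor targets were split, with 6 higher and 9 lower of 27, the same when adjusted over the list alone, 3 and 11 after median-ratio rescaling and 3 and 10 after quantile normalization (camera adjusted p = 0.0511; median -0.0032 log2, mean -0.065). Without sgEmpty replicate 2 or sgSETD1A replicate 2, 3 were higher and 8 lower. The list was called lower without sgEmpty replicate 2, sgEmpty replicate 3, sgSETD1A replicate 1 or sgSETD1A replicate 2 (camera adjusted p = 0.0407, 0.0441, 0.0425 and 0.0313), without a filter (0.0498) and with a mean of at least 5 TPM (0.0218); over 16 alternatives with the preset correlation or ranks the value ran from 0.0218 to 0.147. With an estimated correlation the list was not called (adjusted p = 0.482). AREG, a growth factor, went from 117.4 ± 6.55 to 63.6 ± 3.13 TPM (SD, n = 3), GREB1 changed by -0.84 and the amino acid transporter SLC7A5 by -0.63 log2, while the receptor kinase RET rose by 0.74. Of 23 luminal markers, 10 rose and 4 fell (11 and 4 when adjusted over the list alone), and 4 and 6 after median-ratio rescaling (camera adjusted p = 0.933). TFF3 rose by 0.54 log2, and AGR2, TFF1 and PRLR changed by -0.39, -0.32 and -0.32. Of 11 tested basal markers, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.993, direction down beside a median of 0.079 log2): KRT15 by 0.71, ITGA6 by 0.59, ACTA2 by -0.48 and OXTR by -0.45 log2. Of 24 mesenchymal markers, 8 were tested and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.234): COL6A1 by 0.62, TWIST1 by 0.50, COL6A2 by 0.47 and FN1 by 0.38 log2. The median of the 8 was 0.30 log2, against 0.0079 without a filter on low TPM, where 5 of 19 rose. Among 17 immune cell markers only CD68 was tested, at 1.48 ± 0.27 and 1.36 ± 0.017 TPM (SD, n = 3; limma adjusted p = 0.659), and PTPRC stayed at or under 0.191 TPM in each library.

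Of 27 p53 targets, 7 rose and 2 fell, the same when adjusted over the list alone, and 4 and 6 after median-ratio rescaling (camera adjusted p = 0.946). Only 1 fell without sgEmpty replicate 1, sgEmpty replicate 3 or sgSETD1A replicate 3 (6, 7 and 5 rose). GDF15 rose by 0.48, PLK2 by 0.30 and TP53INP1 by 0.24 log2. Of 21 apoptosis regulators, 8 rose and none fell, with 4 and 1 after median-ratio rescaling (8 when adjusted over the list alone; camera adjusted p = 0.366). After quantile normalization 5 rose and 1 fell, and without sgEmpty replicate 2 or sgSETD1A replicate 2, 5 rose and none fell. BAK1, a protein that opens the mitochondrial outer membrane, rose by 0.60 and BMF by 0.32 log2. Of 24 measured genes of senescence-associated secretion, 9 were tested. Of these 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.215), with IGFBP3 and GDF15 among the rises, TIMP2 at 0.35 log2 and AREG as the fall. The median of the 9 was 0.19 log2, against 0.10 without a filter on low TPM, where 6 of 18 rose and 1 fell. Of 26 genes of the integrated stress and unfolded protein responses, 7 rose and 9 fell, the same when adjusted over the list alone, 2 and 11 after median-ratio rescaling and 4 and 11 after quantile normalization (camera adjusted p = 0.176). Without sgSETD1A replicate 2, 4 rose and 7 fell. PSPH and PHGDH, enzymes of serine synthesis, changed by -0.70 and -0.35 log2, while DDIT3 rose by 0.36 and VLDLR by 0.32.

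Of 33 nuclear-encoded genes of oxidative phosphorylation, 6 rose and 10 fell (8 and 10 when adjusted over the list alone, 2 and 10 after either rescaling), with a median of 0.042 and a mean of -0.019 log2. The list was not called with TPM as deposited (camera adjusted p = 0.215) and was called lower after median-ratio rescaling (camera adjusted p = 0.0473) and after quantile normalization (0.0376); over 16 alternatives with the preset correlation or ranks the value ran from 0.0376 to 0.376. With TPM as deposited and an estimated correlation the list had an adjusted p = 0.666. COX6C went from 864.7 ± 12.9 to 1612 ± 57.9 TPM (SD, n = 3), a rise of 0.90 log2 (limma adjusted p = 4.21e-07), against falls of SDHC (-0.61), NDUFB5 (-0.47) and ATP5O, now ATP5PO (-0.41). Of 12 haem synthesis genes, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.234, direction down beside a median of 0.040 log2), and none rose after either rescaling. Without sgEmpty replicate 1, sgEmpty replicate 3 or sgSETD1A replicate 1, 1 rose, and without sgEmpty replicate 2, sgSETD1A replicate 2 or sgSETD1A replicate 3 none did; 3 fell each time. UROS changed by -0.59 and TMEM14C by -0.29 log2. Of 36 genes of ribosome biogenesis and MYC targets, 11 rose and 1 fell, the same when adjusted over the list alone, and 5 and 5 after median-ratio rescaling (camera adjusted p = 0.612). SRM rose by 0.30, ODC1 by 0.27 and NOP56 by 0.27 log2, and NOB1 changed by -0.31. Of the 13 mitochondrially encoded transcripts listed, 0 were among the symbols analysed. None of the 5 lists called by camera was called with an estimated correlation.

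The rule for named genes also took 9 genes whose call did not hold in every setting. Near the threshold stood PALB2 (-0.30 log2), which lost its call without sgEmpty replicate 3 (limma adjusted p = 0.0515), and PFKFB4 (0.34), which lost it without sgEmpty replicate 2 (0.0536) and sgSETD1A replicate 3 (0.0503). SKP2 (0.36) lost it without sgEmpty replicate 2 (limma adjusted p = 0.0544) or 3 (0.0688), and GADD45A (0.27) without sgEmpty replicate 1 (0.0595) or 2 (0.0560) or sgSETD1A replicate 3 (0.0601). ATM (-0.29) lost it without sgEmpty replicate 2 (limma adjusted p = 0.132) or 3 (0.106) or sgSETD1A replicate 2 (0.117) or 3 (0.0851). CCNC (0.17) lost it without sgEmpty replicate 1 (limma adjusted p = 0.0893) or 3 (0.0886) or sgSETD1A replicate 1 (0.0662) or 3 (0.0931), and BCL2L2 (0.27) without sgEmpty replicate 1 (0.145) or 2 (0.113) or sgSETD1A replicate 2 (0.135) or 3 (0.133). ALAS1 (0.20) lost it without sgEmpty replicate 1 (limma adjusted p = 0.128) or 2 (0.117) or sgSETD1A replicate 1 (0.0942), 2 (0.0516) or 3 (0.0653). PMAIP1 (0.34) lost it without any 1 library, with limma adjusted p of 0.0548, 0.0872 and 0.0556 for sgEmpty replicates 1 to 3 and 0.0765, 0.0604 and 0.0606 for those of sgSETD1A. Median-ratio rescaling also ended the calls of SKP2, GADD45A, CCNC, BCL2L2, ALAS1 and PMAIP1, and quantile normalization those of SKP2, CCNC, BCL2L2, ALAS1 and PMAIP1. Testing without a filter on low TPM ended those of ATM, SKP2, CCNC, BCL2L2 and ALAS1, and leaving out the mean-variance trend those of CCNC, BCL2L2 and ALAS1. Over all alternatives the highest limma adjusted p was 0.231 (CCNC) and the lowest 0.00386 (PMAIP1).

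The second comparison asked which guides were lost between day 0 and day 14, and so which tiled genes, and which parts of SETD1A, the cells lost guides against. Guides against SETD1A fell: over 628 guides the median change was -1.23 log2 relative to the HGLibA guides (95% interval -1.33 to -1.14), and 59.7% of them (55.8% to 63.6%, exact) fell at least 1 log2. That median lay below all 10000 random lists matched on day 0 reads. These lists were drawn from all 5991 guides, of which 2435 were against KMT2D. They rank a target within the pool and not against neutral guides. Guides against its paralog SETD1B changed less, with a median of -0.25 (-0.28 to -0.21) over 744 guides and 7.66% falling at least 1 log2. KMT2D guides had the lowest median of the tiled genes, -1.43 (-1.49 to -1.38) over 2435 guides, and also lay below all random lists. KMT2C guides had a median of -0.84 (-0.88 to -0.79) over 1331 guides, and guides against BOD1L1 one of -0.64 (-0.72 to -0.56) over 618. These lay at the other end of the random lists, at percentile 99.5 for KMT2C and 100 for BOD1L1, as did SETD1B at 100. KMT2C and BOD1L1 guides still fell relative to the HGLibA guides, by at least 1 log2 in 40.5% and 32.0% of cases.

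The 200 HGLibA guides had a spread of 0.46 log2 (SD over guides), and 4 of them fell at least 1 log2. Of 25 guides against the essential genes RPA3, PCNA, POLR2A, POLR2L and SF3B3, 24 fell at least 1 log2, with a median of -3.63. The 5 guides that cut AAVS1, a locus used as a safe harbour, had a median of -1.01 (range -1.46 to 0.18), near that of SETD1A guides. The level of every median depended on its reference. With totals alone and no centring SETD1A was at -0.49, KMT2D at -0.69, KMT2C at -0.10, BOD1L1 at 0.10 and SETD1B at 0.49. Centred on all guides SETD1A was at -0.31, SETD1B at 0.67, BOD1L1 at 0.28 and KMT2C at 0.072. The sign thus turned for SETD1B, BOD1L1 and KMT2C, and not for SETD1A and KMT2D. The difference between SETD1A and SETD1B guides does not depend on such a shift.

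**Figure D3:**
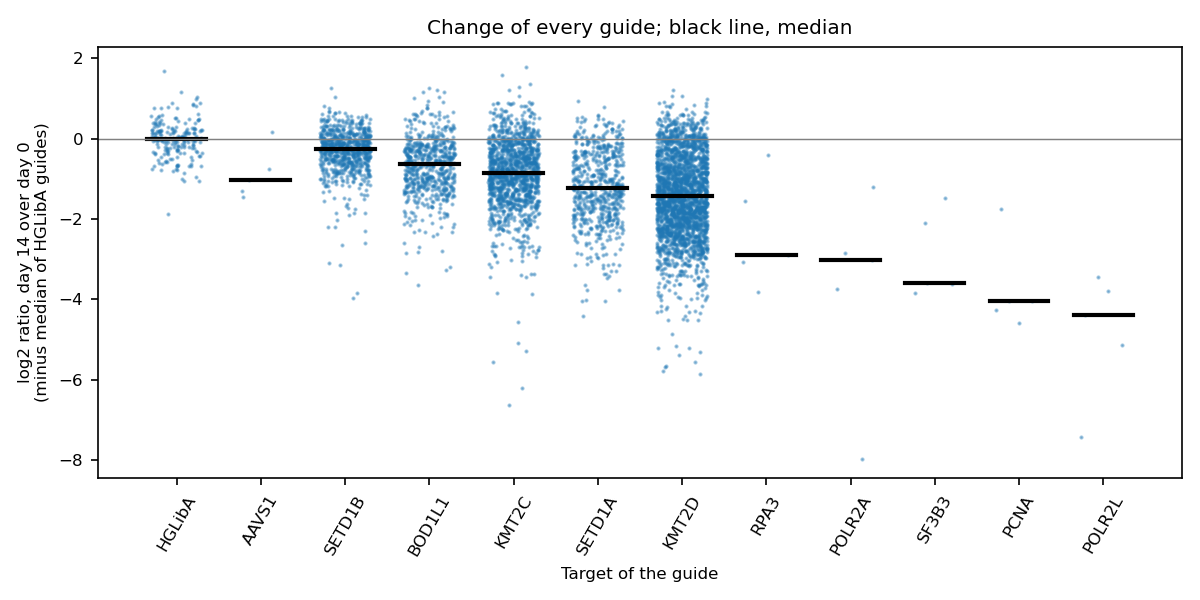
log2 ratio of CPM, day 14 over day 0, minus the median of the HGLibA guides, for each guide by target; black lines are medians. SETD1B guides lie around -0.25, SETD1A guides around -1.23 and essential-gene guides lowest.

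Relative to the HGLibA guides, 15 of 18 windows of 100 residues in SETD1A had a median of -1 log2 or lower. That count depends on the centring: with totals alone, or centred on all guides, 0 windows reached -1 and 16 of 18 lay below 0, with lowest medians of -0.95 and -0.78. The lowest was residues 1 to 100, at -1.69 (95% interval -2.18 to -1.35, 41 guides), at percentile 0.3 of random lists of SETD1A guides, which does not allow for its choice as the lowest of 18 windows. Next were residues 1501 to 1600 (-1.43, 40 guides, percentile 10.8) and 401 to 500 (-1.38, 26 guides, percentile 25). The windows at the C-terminal end, where the catalytic SET domain lies, had medians of -1.43, -1.23 and -1.12. Those of -1.43 and -1.23 were close to that of the whole gene. The window at -1.12 held 6 guides, with a 95% interval of -1.76 to 0.58, too wide to place it. Guides were lost least at residues 1301 to 1400, at -0.26 (-1.17 to 0.021, 22 guides), and 1101 to 1200, at -0.61 (38 guides). Both windows were chosen for naming after their values were seen.

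The 5 SETD1A guides that fell most, in an order that depends on the pseudocount of 1 CPM for the guide with 0 reads, were at residues 105, 5, 42, 64 and 78. The guide at residue 105 went from 1193 to 85 reads, a change of -4.42 log2. Those at residues 42, 64 and 78 went from 1202 to 114, from 2083 to 208 and from 859 to 97 reads. The guide at residue 5 went from 90 reads to 0. The exact 95% Clopper-Pearson interval of its change relative to the HGLibA guides ended at -5.34 log2, counting error of both libraries included. In the other tiled genes the lowest windows were residues 201 to 300 of KMT2D (-2.34, 7 guides), 301 to 400 of KMT2C (-1.81, 6 guides, 95% interval -3.87 to 0.39), 1 to 100 of BOD1L1 (-1.32, 16 guides) and 201 to 300 of SETD1B (-0.40, 20 guides).

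**Figure D4:**
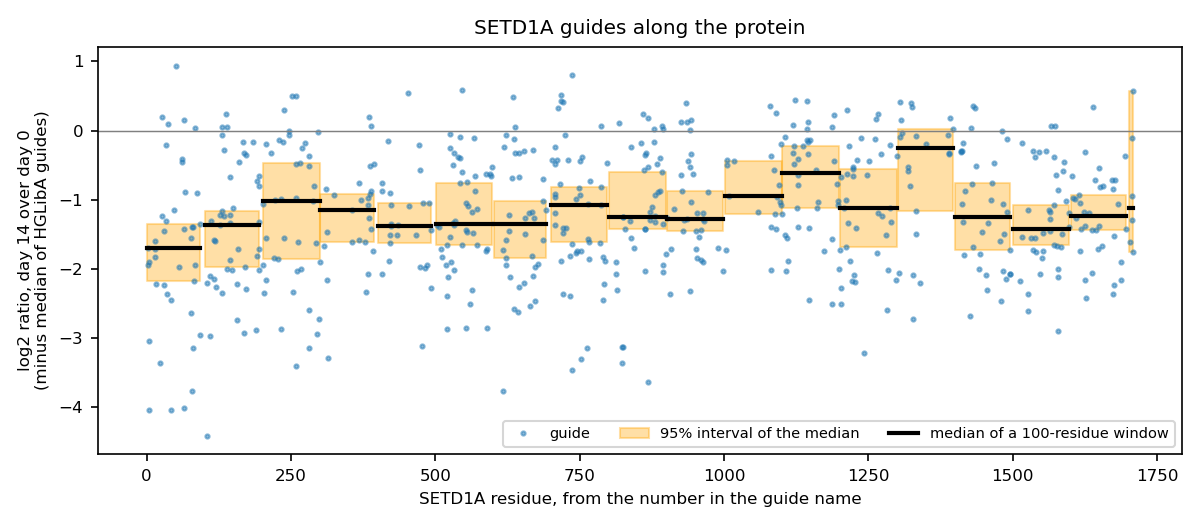
SETD1A guides by residue, with the log2 ratio of day 14 over day 0 minus the median of the HGLibA guides; black lines are medians of 100-residue windows and shading is the 95% interval of the median. The windows run from -1.69 at residues 1 to 100 to -0.26 at residues 1301 to 1400.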

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

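Of 101 called named genes, 92 kept their call and direction in each of the 15 alternative fits that tested them, where a mean of at least 5 TPM left 96 of all 104 named genes; ATM, SKP2, CCNC, ALAS1, BCL2L2, PMAIP1, GADD45A, PALB2 and PFKFB4 lost it in at least 1 setting. The SETD1A transcript change stayed past the threshold, between -0.79 and -0.56 log2. The cause was not tested for any of the shifts below, except where the setting itself removes genes, libraries or a shared offset.

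Leaving out each library gave 2361 to 3459 higher and 1288 to 1616 lower genes, 14 to 25 higher and 24 to 29 lower by at least 1 log2, and 2 to 3 lists called in each direction. The number of genes higher was 1766 with median-ratio rescaling and 2142 with quantile normalization. Genes higher by at least 1 log2 numbered 82 with a pseudocount of 0.1 and 6 with 5, and genes lower 50 and 6. With an estimated correlation 0 lists were called higher and 0 lower, and with fry, which does not compare a list with other genes, 11 higher and 5 lower. Whether replicate numbers pair the libraries could not be settled with 3 libraries per group. Correlations of deviations between same-numbered libraries were 0.085, -0.10 and 0.17. Replicates 1 and 3 of sgEmpty and replicate 3 of sgSETD1A correlated best with their own number, and the others did not. A replicate block gave 3103 higher and 1539 lower genes, and with it ATM, CCNC and ALAS1 were not called (limma adjusted p = 0.0584, 0.0519 and 0.0526). Rescaling without mitochondrially encoded transcripts was not run, since 0 of them were among the symbols analysed.

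Uncalled lists near zero turned the test's direction, with these medians. Basal markers stood at 0.079 without a filter, without the trend, with the block, with fry and on ranks, at 0.0015 with median-ratio rescaling, 0.15 without sgEmpty replicate 1 and 0.078 without sgSETD1A replicate 3; without each of the other libraries the direction did not turn, and the lowest of those medians was 0.019. p53 targets stood at 0.0063 with median-ratio rescaling and 0.084 without the trend and on ranks, luminal markers at -0.013 and 0.066 with median-ratio rescaling and without the trend, ribosome biogenesis at -0.027 with median-ratio rescaling and SETD1 and KMT2 complexes at 0.044 with fry. CD68 stood between -0.12 and 0.023 log2 without 1 library each, the last without sgEmpty replicate 1.

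The screen depended on centring, which subtracts one value from every guide. Centred on all guides, medians were -0.31 for SETD1A, 0.67 for SETD1B, 0.072 for KMT2C, -0.52 for KMT2D, 0.28 for BOD1L1 and 0.52 for the lowest SETD1B window. With totals only they were -0.49, 0.49, -0.10, -0.69, 0.10 and 0.34. KMT2D was at -1.35 with a pseudocount of 10, and the mean over SETD1B guides was -0.31. The lowest SETD1A window stood at -1.83 with windows of 50 residues and -1.59 with 200.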

Other observations

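Tests of scaling, expression, immune cells, cutting, copy number and read numbers, and of splits of the libraries, were chosen after the results were seen. Grouping genes by the start of their symbol, also chosen afterwards, gave 69 families of at least 15 tested genes. Mitochondrial ribosomal protein genes of the MRPL family fell in 19 of 47 cases and rose in 5, with a median of -0.080 log2 (camera adjusted p = 2.10e-05, and 0.279 with an estimated correlation). Those of the MRPS family did not share this: of 29, 6 rose and 7 fell, with a median of 0.031 log2 (camera adjusted p = 0.287). Kinesin genes (KIF) rose in 16 of 29 cases and fell in 1, with a median of 0.20 log2 (camera adjusted p = 0.0115; adjusted p = 0.463 with an estimated correlation). The mitosis list also holds kinesin genes, KIF23 among them, so this rise is not independent of that list.

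Guides along the tiled genes differed in how much their loss varied with position. The SD of window medians in SETD1A was 0.32 log2, and 2% of 1000 shuffles of its guides gave as much. In KMT2D it was 0.33 (0.6% of shuffles) and in BOD1L1 0.29 (0.4%), while KMT2C (0.24, 24.2%) and SETD1B (0.089, 42.9%) did not stand apart from shuffled guides. The 188 pairs of guides that share a name differed by a median of 0.60 log2, against 0.80 for random pairs of guides of the same gene.

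Called genes that fell by at least 0.5 log2 lay close to another gene more often than other genes. Of 327 such genes with a neighbour in the RefSeq table (95.9% of 341), 62.4% had the end of another protein-coding gene within 1 kb or overlapping, against a median of 44.6% over 10000 random lists matched on expression and 54.4% at most. Called genes that rose by at least 0.5 log2 had such a neighbour in 32.4% of 376 cases. Short gene span was argued against as the whole cause. Lists matched on both expression and gene span reached 55.7% at most, with a median of 46.5%. Local gene density was not matched. A neighbour within 1 kb is itself a measure of density, so dense regions could not be told apart from it. A hypothesis is that transcripts from closely spaced genes may depend more on SETD1A; orientation was not analysed here and the builds of the table and the data differ. Among 165 tested neighbours 42 rose and 39 fell, with a median of 0.014 log2, against 3327 and 1605 of all 11885 tested genes, with a median of 0.073. Neighbours that were themselves among the fallen genes were not removed. The falls and the median may thus count chosen genes again, and they do not bear on the hypothesis. The hypothesis that longer genes fall more found no such trend: across 11729 genes, which are not independent, Spearman's rho of change with gene span was 0.053.

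Ribosomal protein genes were lower as a list. A scaling shift shared by all genes is argued against, since median-ratio rescaling left the list at a median of -0.23 log2 and quantile normalization at -0.094. High expression alone stays open: 0 of 10000 lists matched on expression had a median as low, but the 20 bins are coarse at the list's median of 2639 TPM. The 100 highest genes of each library, not separated from this list, took 37.3% to 38.2% of TPM in sgEmpty. In sgSETD1A they took 35.4% to 35.5%. Loss of signal in short genes is argued against only as the whole cause: 421 other abundant genes with a span under 5 kb had a median of 0.028 log2 (95% interval -0.00066 to 0.046), above -0.073, which is 0.5 of the list's median, but below the 0.073 of all tested genes. The shortest of 5 classes of span had a median of 0.046 log2 with 413 falls, and the longest 0.085 with 235, so a part played by short genes stays open, as does an effect of SETD1A loss; span stands in for transcript length, which was not used here, and 20 of the 45 list members lie under 5 kb.

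Interferon genes were higher as a list, and remained at a median of 0.50 log2 after median-ratio rescaling, which argues against scaling. Immune cells in the cultures would bring PTPRC, whose highest level in any library was 0.191 TPM. DNA cutting as such cannot be told apart from loss of SETD1A, because the empty guide cuts nothing and no cutting control library was analysed here; the p53 target list gave a camera adjusted p of 0.946, which does not decide it.

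SETD1A guides were lost by day 14. A cost of cutting that is equal at any site is argued against as the whole cause by SETD1B guides. Their median was -0.25 log2, the least lost of the tiled genes. The 5 AAVS1 guides, which also cut, ranged from -1.46 to 0.18, which holds the SETD1A median. A cost of cutting that differs between sites thus stays open. Low read numbers are argued against by the SETD1A guides with more reads at day 0, with a median of -1.20. The copy number of the cut locus cannot be told apart from a need for SETD1A, since copy number of this line was not used here and the 5 AAVS1 guides, at a median of -1.01, fell nearly as far.

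The count of 4932 genes called between the real groups compares with 0 in the highest of the other splits (limma; 66 to 551 genes at an unadjusted p under 0.05, against 6041). The real split was 1 of 10 splits of the 6 libraries, too few for a share under 0.05. Each other split puts libraries of both groups on each side. A difference between groups then widens the spread within sides, so the 0 does not measure noise.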
